A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

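RNA-seq libraries from primary human hepatic stellate cells (the collagen-producing pericytes of the liver) were analysed. All 12 libraries came from cells of 1 commercial donor, transfected with an oligonucleotide at 150 nM and harvested after 72 h, per the labels' protocols. An LNA (a chemically locked antisense oligonucleotide that directs RNase H cleavage of a complementary RNA) was used against the long non-coding RNA TILAM, and a small interfering RNA (siRNA) against PML. Each had its own non-targeting control. The 4 groups held 3 libraries each: TILAM LNA, control LNA, PML siRNA and control siRNA. One LNA and one siRNA were used per target, so an effect of the sequence apart from its target cannot be separated from loss of the target. The labels call the samples triplicates and do not say whether they are separate cultures. P-values therefore measure the spread between these libraries, which may be technical. The 6 mouse samples of the series were not analysed here.

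Per the labels' protocols, total RNA with an RQN above 9 went through poly-A selection and a directional kit and was sequenced on a HiSeq instrument. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.10a, RSEM 1.3.3 and DESeq2 1.38.3 were named with the GRCh38 genome build. The annotation release, the strand setting of the counting and the trimming were not given in the sources used here. Each library had 1 deposited table of RSEM values per gene, and per the file headers it held expected counts, TPM, FPKM, a length and an effective length. The expected counts were estimated by the authors' RSEM run and were not normalized, and the TPM values were normalized for library size and length by the same run. Expected counts were rounded to whole numbers before testing, since up to 14.1% of the counts above 0 in a library were not whole. Each table had 62757 gene rows. The 572 rows of Y-linked genes, their pseudoautosomal copies, XIST and its antisense partner were left out, which kept 62185. Of these, 57763 (92.9%) matched a GENCODE release 29 gene by identifier, from which GRCh38 positions, strand and gene type were taken.

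Genes with enough counts in at least 1 group were kept with filterByExpr, leaving 17651. Libraries were scaled with TMM. One edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust dispersion, 8 residual degrees of freedom) was fitted to all 12 libraries, with group as the only factor. Contrasts compared TILAM LNA with control LNA, PML siRNA with control siRNA, the difference between these effects, and control LNA with control siRNA. P-values were adjusted over all genes tested by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" refer to called genes only. CPM values are scaled by the TMM factors and are given as mean ± SD over 3 libraries. PCR duplicates could not be told from separate molecules, so counting intervals cover counting error only. A fold against a group with 0 fragments is a lower bound against a floor of 3 fragments over the group. The smallest p an exact two-sided permutation test of 3 against 3 libraries can give is 0.1.

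Gene lists were fixed before the data were examined: extracellular matrix, collagen processing and crosslinking, matrix proteases and inhibitors, myofibroblast contractile genes, TGF-beta pathway components, TGF-beta target genes, YAP/TEAD target genes, stellate cell quiescence, PML bodies and SUMO, interferon-stimulated genes, inflammatory cytokines and NF-kB, p53 target genes, cell cycle and proliferation, cholesterol synthesis and uptake, integrated stress response, unfolded protein response, hypoxia and glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation, and markers of hepatocytes, endothelium, macrophages, cholangiocytes, lymphocytes, mesothelium and portal fibroblasts. Some genes are in more than 1 list. Of the 26 lists, the 23 with at least 5 tested members were compared with all other genes by camera (limma) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated per list was an alternative. List counts are given at the adjustment over all genes and adjusted over the list alone.

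Named genes followed a rule fixed before the data were examined: the target genes; the 10 largest rises and falls of each knockdown among called genes with a mean of at least 5 CPM in the higher group, non-overlapping libraries and a gene symbol that is not a clone, LINC, antisense or pseudogene name; up to 4 members per list with the smallest adjusted p; and fixed fibrosis genes whatever their p, among them COL1A1, COL1A2, COL3A1, ACTA2, TAGLN, TIMP1, TGFB1, TGFB2 and CCN2. Some results for genes that this rule selects are left out of the text. The 5 largest each way were taken for the other contrasts and for genes called in both knockdowns. Apart from these, the list members named for the difference between the effects and for the controls lie outside this rule. So does MKI67 in PML siRNA. Overlap of calls was compared with independent lists by Fisher's exact test across genes. The knockdowns shared no control library.

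On data simulated for the 17651 genes, the test recovered 67.2% of genes changed 2-fold in the TILAM comparison and 62.7% in the PML comparison. Of all calls in those runs, 4% and 5.5% were false. Every library was drawn from the means of the control group, with the dispersions and library sizes of the data and with genes independent. Few genes were changed, 67 of them for the 2-fold recovery. In the real TILAM LNA comparison 65.6% of genes were called, so these shares may not carry over to it. Alternatives tried were RLE and upper-quartile scaling, library totals only, DESeq2 1.42.0, no filter and a stricter filter (5 CPM in 3 libraries), only the libraries compared, the replicate number as a block, effective-length offsets, protein-coding genes only, genes of a genomic span under 100 kb only, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.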

Results

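Gene expression was measured by poly-A RNA-seq in primary human hepatic stellate cells transfected with an LNA against TILAM, a control LNA, an siRNA against PML or a control siRNA, with 3 libraries per group. The total expected count per library was 13688721 to 27886868, with the lowest total in TILAM LNA replicate 3. Library structure followed the groups. The first principal component of log2 CPM held 70.9% of the variance and set the TILAM LNA libraries at 122 to 174 apart from the other 9, which lay at or below -29.4. TILAM LNA replicate 3 lay at 122, nearer to the other groups than the other two. Control siRNA replicate 3 stood apart from its group: its counts differed from those of replicates 1 and 2 with a chi-square per degree of freedom of 86.2 and 71.3, against 3.72 between replicates 1 and 2. Every pair of replicates differed by more than counting error.

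The first question was whether each oligonucleotide lowered its target. PML, which encodes the scaffold protein of PML nuclear bodies (GRCh38 chromosome 15, 73994673 to 74047812), was at 24.3 ± 3.06 CPM in PML siRNA and 142 ± 42.0 CPM in control siRNA, or 17.2% of the control level. Its log2 fold change was -2.54 (SE 0.191, adjusted p = 2.84e-06 in edgeR), and the libraries did not overlap. Control siRNA replicate 3 had the highest PML level, 190.1 CPM, against 116.5 and 118.2 CPM in replicates 1 and 2. The files hold no gene named TILAM. A RefSeq table of GRCh38.p14 places TILAM on chromosome 17 at 50214694 to 50215420, inside the lincRNA gene ENSG00000249406 (50208944 to 50215922, plus strand), which lies near COL1A1 (50183289 to 50201632, minus strand). The reads of ENSG00000249406 cannot be assigned to the TILAM transcript itself. It had 33, 19 and 36 fragments in the control LNA libraries and 0 fragments in each TILAM LNA library, at least 37.8-fold lower against a floor of 3 fragments over the group (adjusted p = 2.33e-05). In control siRNA it had 89, 82 and 79 fragments and in PML siRNA 42, 48 and 21, a log2 fold change of -1.25 (SE 0.396, adjusted p = 0.0369). ENSG00000249406 was also lower in control LNA than in control siRNA, at 1.43 against 3.84 CPM (log2 fold change -1.45, SE 0.404, edgeR adjusted p = 0.0215). At 1.62 CPM, PML siRNA was near the control LNA level, so the lower level is not particular to PML siRNA. PML also fell in TILAM LNA, to 50.6 ± 9.23 CPM from 107 ± 1.34 in control LNA (log2 fold change -1.09, SE 0.181, adjusted p = 2.14e-04). With 3 libraries per group an exact permutation test cannot go below p = 0.1 for any of these genes.

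**Figure D1:**
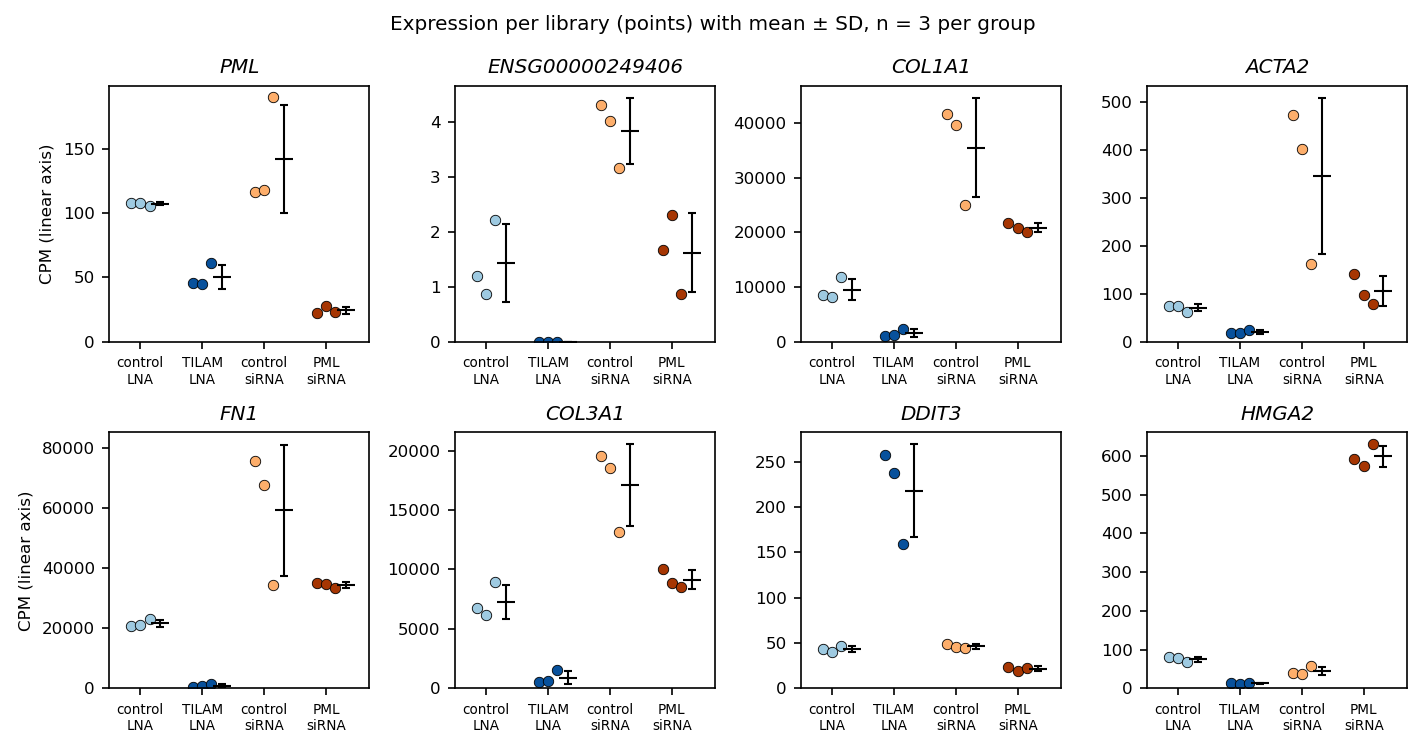
Expression in CPM (TMM-scaled, linear axes from 0) of 8 genes in each library of the 4 groups; points are libraries, and the bar beside them is the mean ± SD (n = 3). ENSG00000249406 was at 0 in the 3 TILAM LNA libraries, COL1A1 and FN1 were lowest there, and HMGA2 was at 598 ± 28.0 CPM in PML siRNA against 45.0 ± 11.2 in control siRNA.

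The TILAM LNA comparison asks which genes change when the lncRNA that the study links to liver fibrosis is targeted. Of 33 extracellular matrix genes 30 fell and 1 rose in TILAM LNA, and of 20 contractile genes 13 fell and 2 rose. Neither list was called with an estimated correlation. FN1, which encodes fibronectin, was at 863 ± 548 CPM against 21590 ± 1205 (log2 fold change -4.65, SE 0.428). COL1A1, which encodes the main chain of type I collagen, was at 1605 ± 694 against 9538 ± 1965 CPM (log2 -2.57, SE 0.288, adjusted p = 6.72e-06), and COL3A1 had a log2 fold change of -3.02. ACTA2, the alpha-smooth-muscle actin that marks activated stellate cells, fell from 71.4 to 20.6 CPM (log2 -1.80, SE 0.357, adjusted p = 0.00112). DDIT3, the stress-induced transcription factor CHOP, rose from 43.2 ± 3.13 to 218 ± 51.6 CPM.

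Of the 17651 genes tested, 11587 (65.6%) were called, 6038 higher and 5549 lower in TILAM LNA. At least 2-fold changes numbered 3724 upward and 2203 downward. The split of directions depends on the scaling: of the called genes, 52.1% were higher with TMM, 61.7% with upper-quartile scaling and 72.1% with library totals only. The median log2 fold change of all genes moved from 0.03 to 0.19 and 0.38 in the latter cases, so directions near 0 are relative to the scaling chosen. TILAM LNA also differed in the number of genes seen. It had 23816 to 28171 genes with at least 1 fragment, against 20093 to 21687 in the other groups, and its 20 most abundant genes took 8.20% to 9.75% of the counts against 13.8% to 20.9%.

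The largest rises were of genes with almost no fragments in control LNA. Rises against 0 control fragments were at least 278-fold for PLA2G4F, a cytosolic phospholipase, at least 144-fold for BTLA, a lymphocyte inhibitory receptor, and at least 138.6-fold for ADAM30. For ZNF705A the bound was 139.7-fold and for FOXD4L5 119.5-fold; both belong to families of near-identical copies, so their reads are uncertain. SLC17A8, a vesicular glutamate transporter, was 831-fold higher against 1 control fragment (95% counting interval 149 to 32850). Against 1 or 2 control fragments, LCAL1 was 613-fold higher (169 to 5063), SLC9A4 522-fold (93.4 to 20660), TMEM151B 483-fold (86.3 to 19090) and HDC, histidine decarboxylase, 360-fold (99.4 to 2977). Their mean levels in TILAM LNA ranged from 5.16 to 16.2 CPM. The largest falls were of ARL15 (log2 fold change -5.99, from 11.6 to 0.184 CPM), DLGAP1 (-5.93), MMP16 (-5.24), the chemokine gene CCL7 (-5.20, SE 0.768), PRKCA, protein kinase C alpha (-5.16, from 54.7 to 1.74 CPM), CCL8 (-4.80), FN1, NREP (-4.62), ABI3BP (-4.60) and CENPK (-4.40).

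Among the fixed lists, 1 extracellular matrix gene rose, 30 fell and 2 did neither, of 33 (adjusted over the list alone, 1 rose and 31 fell). Camera placed the list below other genes at an adjusted p of 3.50e-08 with the preset correlation, and at an adjusted p = 0.436 with an estimated correlation. COL4A1 (log2 -2.31), COL8A1 (-1.81), COL4A2 (-1.79) and ELN, elastin, had the smallest adjusted p. The gene that rose was MFAP5 (log2 0.58, adjusted p = 1.84e-04), which went to -0.04 when effective lengths were included. Of 27 collagen processing and crosslinking genes, 1 rose and 22 fell, and 23 fell adjusted over the list alone (camera adjusted p = 1.79e-05, and adjusted p = 0.468 with an estimated correlation). ADAMTS2 (-1.62), the collagen hydroxylase PLOD1 (-1.21) and P3H2 (-2.03) were among them, as was LOXL3 (-1.04). Of 20 contractile genes 13 fell and 2 rose, also adjusted over the list alone, with CALD1 at -2.39, TPM1 at -1.54, PDLIM7 at -1.20 and TGFB1I1 at -1.17 (camera adjusted p = 0.00269, and adjusted p = 0.468 with an estimated correlation). TAGLN fell by 0.93 on the log2 scale. Of 25 matrix proteases and inhibitors 12 fell and 6 rose, unchanged in number when adjusted over the list alone. ADAM12 (-3.50), SERPINE2 (-1.72) and ADAMTS1 (-0.98) fell beside MMP16, and camera gave an adjusted p = 0.0496, or an adjusted p = 0.594 with an estimated correlation. The collagenase inhibitor TIMP1, at 4194 ± 1052 against 4734 ± 462 CPM, was not called (log2 -0.18, adjusted p = 0.372; -0.40 and 0.00680 without TILAM LNA replicate 3; 0.16 with library totals only).

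TGF-beta signalling genes were mostly lower. Of 24 pathway components, 19 fell and 1 rose, also adjusted over the list alone, and of 24 target genes 15 fell and 3 rose (camera adjusted p = 4.14e-05 and 0.00159; both at an adjusted p = 0.436 with an estimated correlation). TGFB1 (-0.99), TGFB2 (-2.46, from 56.6 to 10.4 CPM), the co-receptor ENG (-1.37), SMAD2 (-1.07) and the activin antagonist FST (-2.33) fell. So did the target genes CDH2 (-2.41), SNAI2 (-1.94) and TGIF1 (-0.94). Of 22 YAP/TEAD target genes 13 fell and 3 rose, the same adjusted over the list alone, with CRIM1 at -1.55, F3, tissue factor, at -2.26, TEAD1 at -0.71 and CCN2 at -0.71 (camera adjusted p = 0.0182, and adjusted p = 0.436 with an estimated correlation). Of 17 gene rows of stellate cell quiescence, 4 fell and 2 rose, likewise adjusted over the list alone, and the list was not called (adjusted p = 0.733); with library totals only 4 fell and 6 rose. RGS5 has 2 of these rows. HGF (-3.12), PPARG (-1.32), HHIP (-1.23) and CYGB (-0.81) fell.

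Interferon-stimulated genes were lower as a group: 35 of 40 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 8.39e-08, and adjusted p = 0.594 with an estimated correlation). EPSTI1 (-2.73) and DDX60 (-1.35) fell, while IRF9, a transcription factor of the interferon response, rose (0.77). Of 29 cytokine and NF-kB genes 13 fell and 6 rose, also adjusted over the list alone (adjusted p = 0.149). CXCL12 fell (-2.63) and the NF-kB subunits RELB (1.02) and NFKB2 (0.78) and the adhesion gene ICAM1 (0.83) rose. Of 38 cell cycle genes 28 fell and 2 rose, as they did adjusted over the list alone (camera adjusted p = 1.40e-04, and adjusted p = 0.681 with an estimated correlation), with FOXM1 at -2.41, BUB1 at -2.70, BUB1B at -2.61 and MCM3 at -1.26. Of 24 PML body and SUMO genes 13 fell and 7 rose (adjusted p = 0.158), also adjusted over the list alone, and 7 fell and 10 rose with library totals only, where the median of -0.22 became 0.13; the histone chaperone DAXX rose (0.94) and ATRX (-0.74), HIPK2 (-0.90) and SENP6 (-0.72) fell.

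Stress and metabolic lists went in both directions. Of 28 p53 target genes 14 rose and 3 fell (adjusted p = 0.113), and of 28 integrated stress response genes 12 rose and 6 fell (adjusted p = 0.234), with the same numbers adjusted over the lists alone. SESN2 (2.59), AEN (1.47), BBC3 (1.53), which encodes the pro-apoptotic PUMA, and POLH rose among the former. DDIT3 (2.34), SLC3A2 (2.14) and AARS1 (1.48) rose and the cystine transporter SLC7A11 fell (-1.32) among the latter. Of 20 unfolded protein response genes 10 fell and 3 rose, adjusted over the list alone as well (adjusted p = 0.141), but 5 fell and 9 rose with library totals only, which took the median from -0.19 to 0.16, with HERPUD1 (1.79) and XBP1 (1.08) up and PDIA6 (-0.99) and PDIA3 (-0.67) down. Of 27 hypoxia and glycolysis genes 20 fell and 1 rose, and 21 fell and 2 rose adjusted over the list alone (camera adjusted p = 1.16e-04, and adjusted p = 0.436 with an estimated correlation), with PDK1 at -2.28, PFKP at -2.31, SLC2A1 at -1.22 and HK2 at -0.78. Of 33 oxidative phosphorylation genes 17 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.0274, and adjusted p = 0.659 with an estimated correlation). With library totals only 4 fell and 14 rose, and their median of -0.20 became 0.15; ATP5F1C (-0.80), SDHC (-0.63) and UQCRQ (-0.87) fell. Of 24 cholesterol genes 10 fell and 4 rose, with the same numbers adjusted over the list alone (adjusted p = 0.20), but 3 fell and 9 rose with library totals only, where the median of -0.24 became 0.11. HSD17B7 (1.91) and ACAT2 (1.06) rose and LSS (-1.06) fell. Of 32 cytosolic ribosomal proteins 7 rose and 3 fell, or 2 and 3 adjusted over the list alone (adjusted p = 0.736), and 24 and 1 with library totals only, with RPL3 at -0.61 and RPS9 at -0.51 among the falls and RPS27 at 0.51 among the rises.

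Markers of other cell types did not move as 1 group. Of 9 endothelial genes 5 rose and 2 fell (adjusted p = 0.456): STAB1 (4.25) and CLEC4M, 213-fold higher against 1 control fragment (38 to 8458), rose and TEK fell (-2.19). Of 8 cholangiocyte genes 4 rose, among them KRT7 (0.82) and KRT18 (1.28), and 0 fell (adjusted p = 0.141). Of 6 lymphocyte genes CD79A rose (6.24) and 3 fell, NKG7 by 1.61 on the log2 scale (adjusted p = 0.371). Of 10 portal fibroblast genes 4 fell, among them GREM1 (-1.71) and PI16 (-0.72), and 1 rose (adjusted p = 0.276), but 3 fell and 4 rose with library totals only. These counts were the same adjusted over each list alone. Lists with 4 tested members had summed levels only. Hepatocyte markers were at 12.0 to 24.9 CPM in TILAM LNA and 2.97 to 4.37 in control LNA, with APOA1 (2.56) and TF, 74.5-fold higher against 2 control fragments (20.3 to 620), rising. Macrophage markers were at 8.23 to 13.8 against 5.01 to 5.24 CPM, with PTPRC up (1.55), and mesothelial markers at 14.4 to 16.2 against 14.1 to 20.1 CPM, with WT1 down (-1.09) and BNC1 up (0.78).

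Change in TILAM LNA followed the genomic span of genes. Protein-coding genes under 10 kb had a median log2 fold change of 0.15, those of 200 to 500 kb -0.72, and the 192 genes over 500 kb -1.48 (95% bootstrap interval over genes -1.65 to -1.19), of which 69.3% fell. Over 14245 genes, Spearman's correlation of span with log2 fold change was -0.251 in TILAM LNA, -0.04 in PML siRNA and -0.077 between the controls; genes are not independent replicates. Among the genes named above, ARL15 spans chromosome 5 from 53883945 to 54310582 and PRKCA chromosome 17 from 66302636 to 66810743, while COL1A1 and FN1 are under 100 kb.

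**Figure D2:**
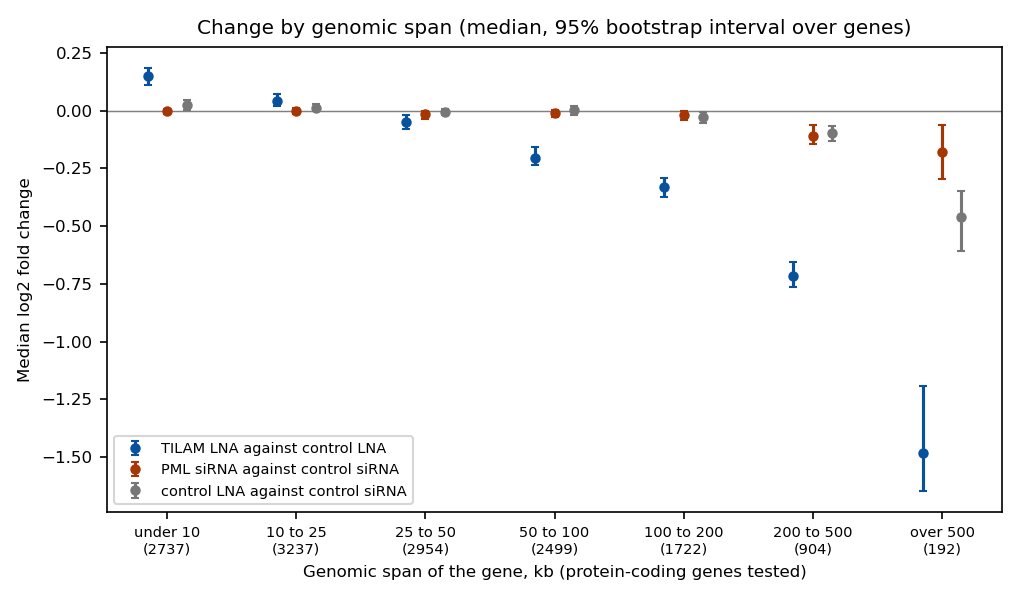
Median log2 fold change of protein-coding genes (vertical axis) by genomic span in kb (horizontal axis, number of genes in parentheses) for the knockdown comparisons and the comparison of controls; bars are 95% bootstrap intervals over genes. The TILAM LNA medians went from 0.15 under 10 kb to -1.48 over 500 kb, where PML siRNA was at -0.18 and the controls at -0.46.

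The PML siRNA comparison asks which genes change when PML is lowered. HMGA2, a chromatin architectural gene, rose from 45.0 ± 11.2 to 598 ± 28.0 CPM (log2 3.73, SE 0.156, adjusted p = 1.15e-08). IL1B, interleukin 1 beta, rose from 228 to 1102 CPM (2.27) and the matrix protease gene MMP10 from 4.41 to 35.9 CPM (3.00). ACTA2 was at 472.9, 402.8 and 161.4 CPM in control siRNA replicates 1, 2 and 3, and at 79.45 to 141.3 CPM in PML siRNA. Replicate 3 of the control thus lay near the highest treated library. The mean of ACTA2 fell from 346 ± 163 to 106 ± 31.8 CPM (log2 -1.70, SE 0.345, adjusted p = 0.00415 in edgeR). Type I collagen genes were lower by less: COL1A2 fell by 0.73 on the log2 scale (SE 0.237, adjusted p = 0.0358), and COL1A1 was at 20800 ± 828 against 35470 ± 9062 CPM, which was not called (log2 -0.77, SE 0.273, adjusted p = 0.0522). IL1B was also higher, and ACTA2 and COL1A1 lower, in control LNA than in the same control siRNA libraries. These moves are therefore not particular to PML siRNA. Lists that camera called in both comparisons with control siRNA moved the same way. Both comparisons subtract the same control siRNA libraries, so a deviation of those libraries would itself move both the same way. Medians in PML siRNA and control LNA were 0.56 and 0.94 for cytokine genes and -0.51 and -0.98 for matrix genes. Quiescence, interferon and cell cycle lists, called in PML siRNA but not in control LNA, moved apart.

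Of the 17651 genes, 4773 (27%) were called, 2288 higher and 2485 lower in PML siRNA, of which 654 and 834 changed at least 2-fold. With library totals only, 61.9% of the calls were higher in place of 47.9%. Control siRNA replicate 3, the library that stood apart, decided several collagen calls. Without it COL1A1 (log2 -0.97, adjusted p = 0.0139) and COL3A1 (-1.06, 0.0308) passed, whereas with all libraries COL3A1 was at -0.90 (adjusted p = 0.0600). Over the alternatives the adjusted p of COL1A1, PML siRNA against control siRNA, ranged from 4.79e-07 with no filter to 0.166 without control siRNA replicate 1. For COL3A1, PML siRNA against control siRNA, it ranged from 6.49e-10 to 0.162 under the same settings. For COL1A2, PML siRNA against control siRNA, the call held without control siRNA replicate 3 (0.00724) and was lost when any other of the 6 libraries compared was left out (adjusted p = 0.0831 to 0.130). TAGLN (-0.27), TIMP1 (-0.02) and TGFB1 (0.27) did not pass, with adjusted p = 0.445, 0.964 and 0.306. For TIMP1 the sign changed with library totals only (0.07).

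The largest rises were of ODAPH (log2 6.65, from 0.15 to 17.1 CPM), ADAMTS18 (4.96), SERPINB4 (4.94, a gene with a near-identical neighbour, so uncertain), IL36G (4.64) and the EGF-receptor ligand TGFA (4.16). NRG1 (4.04, from 7.36 to 122 CPM), CSF2, the cytokine GM-CSF (3.97), DCLK3 (3.79), HMGA2 and F2RL3 (3.55) followed. The largest falls were of SLC6A4, the serotonin transporter (-5.04, from 18.5 to 0.554 CPM), CCL11, the chemokine eotaxin (-4.66), ADH1B (-4.07, one of a family of similar genes), MGARP (-3.94), OLFML1 (-3.80), HTR2A (-3.65), SCN3A (-3.48), MT1G (-3.35, a metallothionein with similar copies), PCDH7 (-3.31) and CACNB4 (-3.27). SERPINB4, TGFA and CSF2 also rose, and CCL11 and MT1G also fell, among the largest changes of control LNA against the same control siRNA libraries. Their moves are therefore not particular to PML siRNA.

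Of 33 extracellular matrix genes 15 fell and 0 rose, and 19 fell adjusted over the list alone (camera adjusted p = 3.32e-05, and adjusted p = 0.628 with an estimated correlation). FBLN5 (-1.43), COL12A1 (-1.45), THBS2 and COL4A1 (-0.63) fell. Of 27 collagen processing genes 11 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 3.87e-04, and adjusted p = 0.628 with an estimated correlation), with SERPINH1, the collagen chaperone HSP47, at -1.66, P3H3 at -1.38, LOXL3 at -1.21 and CRTAP at -0.60. Of 20 contractile genes 5 fell and 2 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.213), with SYNPO2 (-2.20), LMOD1 (-1.71) and PDLIM5 (-0.55) beside ACTA2. Of 25 matrix proteases and inhibitors 10 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0638): MMP14, the membrane-bound collagenase (1.66, from 1331 to 4208 CPM), MMP10 and MMP9 (3.62) rose and ADAMTS1 fell (-1.25).

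Of 24 TGF-beta pathway components 8 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.0479, and adjusted p = 0.628 with an estimated correlation). LRRC32, which presents latent TGF-beta, fell (-2.32), as did FST (-1.79), TGFB3 (-1.46) and TGFB2 (-1.12), and the repressor SKI rose (0.49). Of 24 TGF-beta target genes 7 rose and 6 fell, or 8 and 7 adjusted over the list alone (adjusted p = 0.971), with LRRC15 (2.36) up and CDKN2B (-1.29), CCN2 (-1.25) and TGIF1 (-0.60) down. Of 22 YAP/TEAD target genes 8 fell and 1 rose, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0187, and adjusted p = 0.628 with an estimated correlation), with ANKRD1 at -1.29 and F3 at -1.28 beside CCN2 and TGFB2. Of the 17 quiescence rows 6 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0248, and adjusted p = 0.537 with an estimated correlation): HGF (-2.87), COLEC11 (-1.98), NTF3 (-1.63) and PPARG (-1.50). Of 10 portal fibroblast markers 5 fell and 0 rose, and 8 fell adjusted over the list alone (camera adjusted p = 1.63e-04, and adjusted p = 0.537 with an estimated correlation), with CD34 (-1.81), CLEC3B (-1.11), THY1 (-1.08) and PI16 (-0.94).

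Of 40 interferon-stimulated genes 19 fell and 0 rose, and 24 fell adjusted over the list alone (camera adjusted p = 1.22e-05, and adjusted p = 0.628 with an estimated correlation). STAT2 (-0.76), PSMB9 (-1.36) and XAF1 (-0.67) fell. Of 29 cytokine and NF-kB genes 17 rose and 2 fell, or 19 and 4 adjusted over the list alone (camera adjusted p = 9.55e-05, and adjusted p = 0.628 with an estimated correlation), among them IL1A (2.48), BIRC3 (1.69) and ICAM1 (1.23). Of 28 p53 target genes 16 fell and 1 rose, or 18 and 1 adjusted over the list alone (camera adjusted p = 1.22e-05, and adjusted p = 0.628 with an estimated correlation), with GDF15 at -1.85, KITLG at -1.34, BAX at -0.84 and FAS at -0.83. Of 38 cell cycle genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.63e-04, and adjusted p = 0.628 with an estimated correlation). CCNE2 (2.09), E2F1 and CDC6 (1.00), which act at entry into S phase, rose and PCNA fell (-0.50). MKI67, a marker of dividing cells, was not called (log2 0.69, adjusted p = 0.291): it was at 41.4, 41.3 and 92.5 CPM in control siRNA replicates 1, 2 and 3 and at 83.2 to 105 CPM in PML siRNA, so 1 of the 3 controls lay at the treated level. Of 24 PML body and SUMO genes 8 rose and 2 fell, or 8 and 4 adjusted over the list alone (adjusted p = 0.273), with HIPK2 (0.99), MORC3 (0.48) and SENP2 (0.44) up and PML itself among the falls.

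Of 24 cholesterol genes 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00679, and adjusted p = 0.628 with an estimated correlation), with INSIG1 (1.27), NSDHL (0.86) and FDFT1 (0.58) up. Of 28 integrated stress response genes 13 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.628 with an estimated correlation), with CTH at -1.63, DDIT3 at -1.09, ATF5 at -1.04 and WARS1 at -1.01. Of 20 unfolded protein response genes 8 fell and 2 rose, or 10 and 3 adjusted over the list alone (adjusted p = 0.0780), with CALR at -1.04 and SDF2L1 at 0.70. Lists that were not called also included hypoxia and glycolysis, where 5 fell and 2 rose of 27 and 6 and 3 adjusted over the list alone (adjusted p = 0.695, with 5 falls and 6 rises with library totals only and the median of -0.06 at 0.05; SLC2A3 -2.61, ANKRD37 -1.40). Ribosomal proteins had 3 falls of 32, and 0 adjusted over the list alone (adjusted p = 0.112, the median of -0.09 being 0.01 with library totals only; RPS14 -0.46). Oxidative phosphorylation had 4 rises and 3 falls of 33, also adjusted over the list alone (adjusted p = 0.857; CYC1 0.65, NDUFA9 -0.73).

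Of 9 endothelial markers 3 rose and 2 fell in PML siRNA, also adjusted over the list alone (adjusted p = 0.324): CDH5 (3.15, from 2.42 to 21.3 CPM) and KDR (2.40) rose and TEK fell (-1.38). Of 8 cholangiocyte markers 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.671), KRT19 at 1.40 and KRT7 at -1.62. None of 6 lymphocyte markers was called by edgeR (adjusted p = 0.967 for the list, 0 called adjusted over the list alone). Summed hepatocyte markers were at 2.68 to 4.11 CPM against 2.29 to 2.95, macrophage markers at 5.23 to 6.34 against 4.61 to 8.50, with CD14 down (-1.67), and mesothelial markers at 13.5 to 18.3 against 11.1 to 15.5 CPM.

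**Figure D3:**
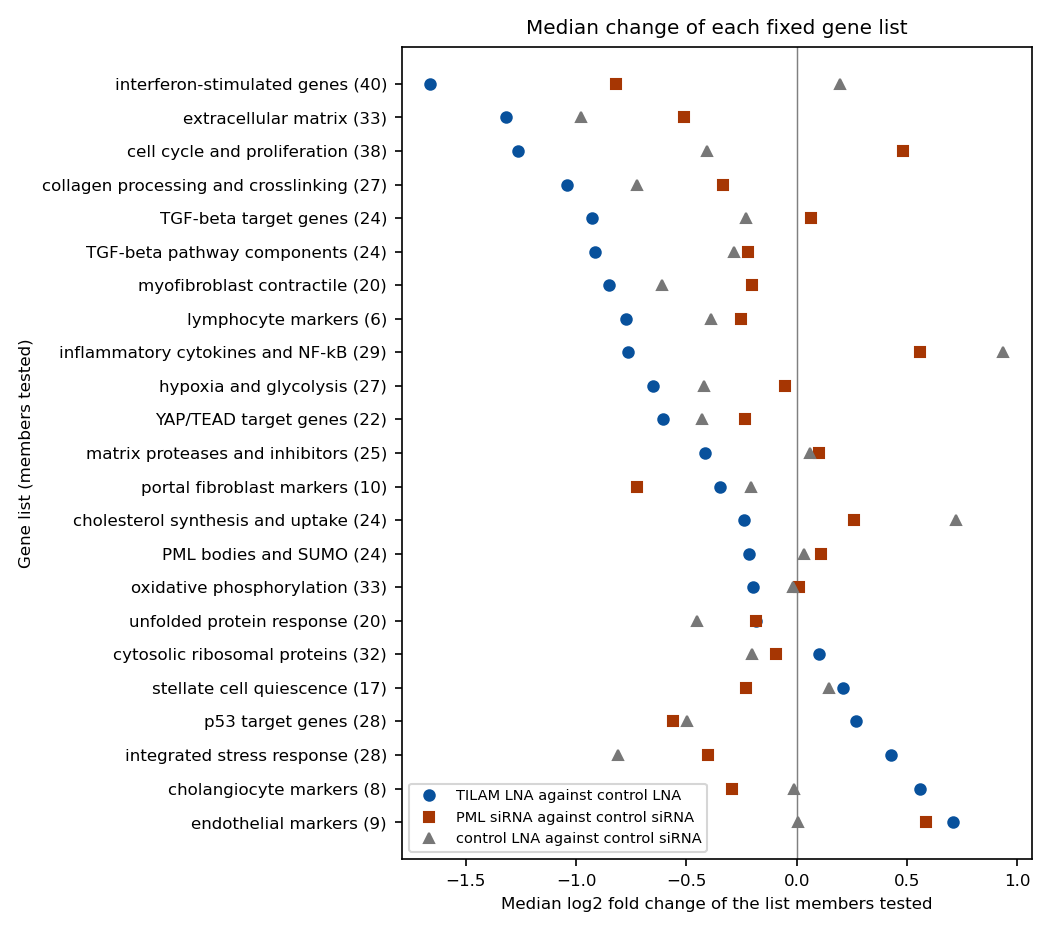
Median log2 fold change (horizontal axis) of the tested members of 23 gene lists (vertical axis, members tested in parentheses) in TILAM LNA against control LNA, PML siRNA against control siRNA, and control LNA against control siRNA. Interferon-stimulated genes had medians of -1.66 and -0.82 in the knockdowns, and cell cycle genes -1.27 and 0.48; the medians of the oxidative phosphorylation, cholesterol, PML body and unfolded protein response lists in TILAM LNA, of ribosomal proteins and hypoxia in PML siRNA, and of 6 lists between the controls changed sign with the scaling.

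The next comparison asked how far the knockdowns changed the same genes. Genes called in the same direction in both numbered 1824. The 1158 that fell in both exceeded the 781.2 of independent lists (Fisher's exact test across genes, p = 1.62e-65), and the 666 that rose in both were fewer than the expected 782.7 (p = 2.77e-08). This balance depends on the scaling: with library totals only, 1383 rose and 602 fell in both. A further 834 fell in TILAM LNA and rose in PML siRNA, against 719.3 for independent lists, and 515 did the reverse, against 850.1. Genes that fell in TILAM LNA thus had more PML siRNA calls than independent lists give in both directions. Genes that rose in TILAM LNA had fewer in both. The Fisher p-values therefore do not measure shared direction alone. Across genes the log2 fold changes had a Pearson correlation of 0.0608 and a Spearman correlation of 0.0723, and genes are not independent. The largest shared falls were of OLFML1 (log2 -4.21 in TILAM LNA and -3.80 in PML siRNA), HGF, LDB2 (-3.57 and -2.74), TNFSF10, the death ligand TRAIL (-2.87 and -2.98), and MT1H, which had 1 fragment in TILAM LNA and similar copies elsewhere (0.111-fold in TILAM LNA, interval 0.00246 to 0.863; -3.14 in PML siRNA). The 5 largest shared rises were of genes with 1 to 3 fragments in control siRNA: XIRP1 (61.4-fold in PML siRNA, 16.7 to 513), IVL, involucrin (62.7-fold, 21.1 to 307), SCAT8 (26.5-fold, 4.38 to 1082), GOLGA6A (19.9-fold, a family gene and uncertain) and SERPINB10 (14.8-fold, 4.77 to 74.4).

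The difference between the effects was tested directly. It was called for 8953 genes, 4368 with the larger log2 fold change in TILAM LNA and 4585 with the larger in PML siRNA (48.8% the former, 58.7% with upper-quartile scaling and 64.1% with library totals only). FNDC7, PLA2G4F, FOXD4L5, SLC17A8 and SLC9A4 had the largest positive differences, with almost no fragments in some groups, so that their fitted size is not a bound. HMGA2 (difference -6.26, SE 0.218), TGFA (-6.43), OPCML (-6.33), ODAPH (-6.58) and SERPINB4 (-7.70) had the largest negative ones. COL1A1 differed by -1.80 (SE 0.387, adjusted p = 0.00184), and for ACTA2 no difference was called (-0.10, SE 0.484, adjusted p = 0.900).

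Camera called 14 lists for this difference, all at an adjusted p = 0.634 with an estimated correlation. Counts here are genes with a larger and a smaller log2 fold change in TILAM LNA than in PML siRNA. Cell cycle genes had 0 and 28 (29 adjusted over the list alone; adjusted p = 2.67e-06), with FOXM1 at -3.05 and BUB1 at -3.37. Cytokine and NF-kB genes had 1 and 20, also adjusted over the list alone (2.69e-04), with IL1B at -2.61 and CXCL12 at -2.40. The p53 targets had 19 and 0 (20 adjusted over the list alone; 2.69e-04), with GDF15 at 3.39 and SESN2 at 2.56, and integrated stress response genes 17 and 2 (17 and 3 adjusted over the list alone; 0.0162), with DDIT3 at 3.43. Extracellular matrix genes had 2 and 21 (3.78e-04; FN1 -3.86), matrix proteases 2 and 12 (0.00310; MMP14 -2.64), interferon-stimulated genes 1 and 13 (0.00187), hypoxia genes 2 and 18 (0.00184; SLC2A1 -1.34) and collagen processing genes 3 and 13 (0.0418; PLOD1 -0.98), all the same adjusted over the list alone. TGF-beta target genes had 3 and 13 (4 and 13 adjusted over the list alone; 0.00536; CDH2 -2.42), TGF-beta components 3 and 13 (3 and 14; 0.0103; ENG -1.02) and contractile genes 1 and 9 (2 and 10; 0.0256). Cholesterol genes had 3 and 12 (0.0179; HMGCS1 -1.40) and oxidative phosphorylation 4 and 13 (0.0294), where library totals only gave 7 and 6 and took the median from -0.24 to 0.01, both unchanged adjusted over the list alone. Lists that were not called were YAP/TEAD targets (adjusted p = 0.321; median -0.17, or 0.07 with library totals only), quiescence (0.433), PML bodies and SUMO (0.144; -0.23, or 0.02), the unfolded protein response (0.459; -0.07, or 0.18), ribosomal proteins (0.347) and the endothelial (0.834), cholangiocyte (0.256), lymphocyte (0.459) and portal fibroblast (0.40) markers.

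The comparison of the controls measured the difference between control LNA and control siRNA libraries of the same cells, without an untransfected group. COL1A1 was lower in control LNA than in control siRNA, at 9538 ± 1965 against 35470 ± 9062 CPM (log2 -1.90, SE 0.281, adjusted p = 3.64e-04). The metallothionein genes MT1G (-5.27) and MT1H (-5.77), which have similar copies, CCL11 (-4.29), ATP10A (-3.99) and PDGFD (-3.93) fell most. SERPINB4 (4.97), CSF2 (4.43), PI3, the protease inhibitor elafin (4.35), PDK4 (3.90) and TGFA (3.88) rose most. In all, 4743 genes were called, 2451 higher and 2292 lower in control LNA, 916 and 553 of them at least 2-fold; with library totals only, 81.9% of the calls were higher in place of 51.7%. Without control siRNA replicate 3 the count was 5182.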

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

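The tests of depth and abundant genes, of the share of silent genes reached and of the response to any LNA were chosen only after the result was seen; depth and abundant genes were first tested separately and then merged.

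More genes were detected in the TILAM LNA libraries: with equal fragments outside the 20 most abundant genes, the lowest TILAM LNA library still had 1.176 times the genes of the highest other library, so depth and abundant genes do not account for it. Silent genes are those without a fragment in any siRNA library. Silent olfactory receptor genes had 0.688 times the fragments per kb of other silent genes (95% interval 0.291 to 1.349), inside the range set beforehand for genomic DNA. As also set beforehand, this ratio left out the densest of the other silent genes, and with them it would be lower. The 100 with most fragments held 34.44% of the fragments of these other genes in TILAM LNA. From control LNA to TILAM LNA the CPM of olfactory receptor genes rose 38.63 times against 28.01 times for other silent genes. Other silent genes, with the densest again left out, were reached 0.478 times as often as an even spread gives (0.469 to 0.488), with mappability not corrected. This argues against an even spread as the whole cause. Genomic DNA stays open, since the interval of the olfactory receptor ratio is wide and the measures point apart. Silent genes within 20 kb past an expressed gene end were reached 1.686 times as often on the same strand (1.53 to 1.865), 73.5% of 565 against 43.6% of 645, so transcription running past gene ends may contribute. This remains a hypothesis, since control LNA had an excess on the same strand too (20.7% against 14.0%) and the neighbours tested are a small part of the 16788 silent genes.

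Genes of long genomic span fell in TILAM LNA. The partial rank correlation of span with log2 fold change was -0.253 given effective length and abundance (-0.271 to -0.238) and -0.228 given GC content (-0.245 to -0.213), so neither transcript length nor GC content accounts for it. Genes over 500 kb moved between the controls by 0.31 of their TILAM LNA change (0.23 to 0.45). Since TILAM LNA was compared with control LNA, a response equal in any LNA is already taken out. The ratio is therefore no share of the fall, and without an untransfected group it may also reflect the control siRNA. Cleavage of long pre-mRNAs by the LNA at sites outside its target and slowed elongation in stressed cells both remain possible; sites for the former could not be searched without the LNA sequence, and the latter was not tested.

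Extracellular matrix genes fell in TILAM LNA. Of 10000 random lists matched for span and abundance, 0.07% had a median as low as -1.32. The matched lists had a median of -0.66 (95% -0.999 to -0.377) and were less abundant by 0.393 log2. These draws take no account of the correlation between list members, estimated at 0.435, with which camera gave an adjusted p = 0.436. The highest median over 4 scalings was -0.976 (upper bound -0.82), so scaling does not account for it. Loss of the target and general toxicity of a single LNA both remain possible, and the same list was also lower in control LNA than in control siRNA.

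In 8 lists the medians had opposite signs in the knockdowns and the difference was called. Only the cell cycle list was called in both, and no difference was called with an estimated correlation (adjusted p = 0.634 for each). With library totals only, cholesterol genes (0.11 in TILAM LNA, 0.35 in PML siRNA) and oxidative phosphorylation (0.15 and 0.11) had medians of the same sign. Bootstrap intervals of the PML siRNA median held both signs for oxidative phosphorylation, TGF-beta targets and matrix proteases. So did those of the TILAM LNA median for cytokine and integrated stress response genes. The adjusted p of the TILAM effect minus the PML effect was 0.005358 for TGF-beta target genes, 2.672e-06 for cell cycle and proliferation, 0.01791 for cholesterol synthesis and uptake, 0.0002688 for inflammatory cytokines and NF-kB, 0.01621 for the integrated stress response, 0.003104 for matrix proteases and inhibitors, 0.02944 for oxidative phosphorylation and 0.0002688 for p53 target genes. Genes whose TILAM effect and PML effect differ numbered 8953. Genes below the low-count filter held 0.225%, 0.218% and 0.118% of the fragments in TILAM LNA replicates 1, 2 and 3, against 0.036% to 0.050% elsewhere.

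Splits of the libraries into other groups were also run. For the genes of the single comparisons the 10 splits are too few for a share under 0.05: TILAM LNA gave 11587 with a highest other of 0, PML siRNA 4773 with 0, and the controls 4743 with 1. For their lists, 4 of the 10 splits gave as many in each comparison, the real one included. The real and highest other counts were 11 and 16, 12 and 15, and 14 and 15. Regrouped libraries thus called as many lists, so chance cannot be excluded for these counts. For the 8953 genes that differ between the effects the highest other was 6716, from a split that keeps the real TILAM grouping, and no split that breaks it gave more than 415, so the count follows whether that grouping is kept and does not test equal effects. The 1824 genes called in both knockdowns had a highest other of 0, but regrouping either knockdown called 0 genes, so this says nothing about chance sharing. For the 14 lists of the difference between the effects chance cannot be excluded (highest other 15).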

How the results depend on the processing

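Library totals only, protein-coding genes only, genes of a span under 100 kb and the alternatives for the lists of the controls were chosen only after the result was seen.

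Gene lists depended on the correlation. With it estimated, 0 lists were called for TILAM LNA in place of 11, 0 for PML siRNA in place of 12, 0 for the difference in place of 14 and 0 for the controls in place of 14, so no list call holds without the preset value. Fry, which tests each list against no change and not against other genes, called 18 lists for TILAM LNA, where most genes changed. Over leave-one-out fits the lists called were 9 to 12, 10 to 15, 12 to 14 and 14 to 15. Of 1050 list results 937 stayed called or stayed uncalled, 84 lost a call, 29 gained one and 0 reversed. A list that changed direction while uncalled in both fits was counted as staying uncalled. The other scalings were not among these list results. Of 4542 gene results 4423 stayed, 101 lost a call, 13 gained one and 5 reversed.

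The reversals were small. TIMP1, TILAM LNA against control LNA, was at -0.175 and went to 0.163 with library totals only. MFAP5, TILAM LNA against control LNA, was at 0.584 and went to -0.035 with effective-length offsets. TIMP1, PML siRNA against control siRNA, was at -0.020 and went to 0.070 with library totals only, 0.019 without PML siRNA replicate 2 and 0.088 without control siRNA replicate 3. It kept its sign at -0.084 without control siRNA replicate 1.

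Leaving out 1 library gave 10192 to 12087 genes for TILAM LNA, 3491 to 5349 for PML siRNA, 7816 to 9947 for the difference, 3260 to 5182 for the controls and 1342 to 2509 for both knockdowns. The fall of PML stayed between -2.67 and -2.27, and the fitted value of ENSG00000249406 between -8.32 and -7.68, which is no measured size because TILAM LNA had 0 fragments; this gene had too few fragments for the stricter filter. Without the low-count filter TILAM LNA gave 12883 genes and with the stricter one 8269. DESeq2 gave 11488, 5298, 9472 and 5312 for the 4 comparisons and effective-length offsets 10161, 3482, 7332 and 3317. Genes of a span under 100 kb alone gave 9004 for TILAM LNA, and protein-coding genes 9485. With the replicate number as a block the counts were 11318, 4572, 8654 and 4393.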

Other observations

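Which lists of the controls to describe was chosen only after the result was seen.

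With the preset correlation, control LNA and control siRNA libraries differed in gene groups of fibrosis. Between control LNA and control siRNA, 25 of 33 extracellular matrix genes fell and 0 rose, or 27 and 1 adjusted over the list alone (camera adjusted p = 4.89e-11, and adjusted p = 0.279 with an estimated correlation), with FN1 at -1.46 and COL3A1 at -1.23. Of 27 collagen processing genes 24 fell and 0 rose, or 24 and 1 adjusted over the list alone (4.79e-12, and adjusted p = 0.275 with an estimated correlation), with SERPINH1 at -1.86. Of 20 contractile genes 14 fell and 0 rose, or 15 and 1 adjusted over the list alone (7.14e-07, and adjusted p = 0.275 with an estimated correlation), with ACTA2 at -2.28, and of 22 YAP/TEAD targets 10 fell and 1 rose, or 12 and 1 adjusted over the list alone (2.38e-05, and adjusted p = 0.263 with an estimated correlation), with ANKRD1 at -1.85. TGF-beta components had 8 falls of 24, or 10 adjusted over the list alone (8.87e-05). TGF-beta target genes had 8 falls and 1 rise, the same adjusted over the list alone (0.0332), and their median of -0.23 was 0.00 with library totals only. Both were at an adjusted p = 0.318 with an estimated correlation.

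Cholesterol genes rose in control LNA, 19 of 24 with 0 falls, or 20 adjusted over the list alone (1.36e-10, and adjusted p = 0.275 with an estimated correlation), with INSIG1 at 1.58 and HMGCS1 at 1.37. Cytokine and NF-kB genes had 17 rises and 2 falls of 29, or 18 and 2 adjusted over the list alone (5.06e-06, and adjusted p = 0.372 with an estimated correlation), with IL1B at 2.39 and CXCL8 at 2.38. Hypoxia and glycolysis had 20 falls of 27, or 23 adjusted over the list alone (6.60e-10, and adjusted p = 0.275 with an estimated correlation), with SLC2A3 at -2.02. The p53 targets had 15 falls of 28, or 19 adjusted over the list alone (4.66e-07; BAX -0.55). Integrated stress response genes had 18 falls and 2 rises, or 19 and 3 adjusted over the list alone (6.85e-07; ASNS -1.84). Unfolded protein response genes had 12 falls and 3 rises and portal fibroblast markers 5 falls of 10, both also adjusted over the list alone (2.68e-04 and 0.00452; CALR -0.87, THY1 -1.45). These 4 lists were at an adjusted p = 0.318 with an estimated correlation, and the median of portal fibroblast markers, -0.205, was 0.025 with library totals only. Ribosomal proteins had 2 falls of 32, or 0 adjusted over the list alone (0.00108, and adjusted p = 0.724 with an estimated correlation), but 0 falls and 2 rises with library totals only, where their median of -0.20 became 0.04. Lists not called were matrix proteases (0.751), quiescence (0.532), PML bodies (0.856), interferon-stimulated genes (0.113), cell cycle (0.113), oxidative phosphorylation (0.856; median -0.02, or 0.21 with library totals only) and the endothelial (0.995), cholangiocyte (0.761; -0.01, or 0.21) and lymphocyte (0.735) markers.

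COL1A1, COL1A2 and COL3A1 were lower in control LNA than in control siRNA, the direction in which they also moved in TILAM LNA. The fall of the extracellular matrix list in TILAM LNA, with a highest median of -0.976 over the scalings, was measured from a control that was itself lower. It may therefore add to an effect of LNA transfection. A fall in control LNA cannot be told from a rise in control siRNA, since COL1A1 was also lower in PML siRNA (20800 CPM) than in control siRNA (35470 CPM). A second LNA and an untransfected group would separate these.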
